A study of Danio rerio with 8 samples.

How the data were processed

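Zebrafish embryos at 53 hours post fertilisation were collected as whole-embryo pools, 4 of wild-type embryos and 4 of iqgap1 homozygous mutant embryos that showed hemorrhage, and total RNA was sequenced. The series' design text gives 20 embryos per pool, while the labels' extraction protocol speaks of single larvae; the difference was not resolved here. Libraries were made after ribosomal RNA depletion with random priming and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name Trimmomatic, STAR 2.7, RSEM and the genome build danRer11, without roles or settings; the annotation and the strand setting are not given in the sources used here.

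The deposited table holds 1293 genes with the authors' log2 fold change (mutant over wild type), its linear fold change as a ratio, a p-value and an adjusted p-value, per the file headers, and 1 value per library. The tool behind the authors' comparison is not given in the sources used here. Every listed gene had a deposited adjusted p of 0.04997 or lower and an absolute log2 fold change of 0.5856 or more, just above the log2 of 1.5. Dividing the adjusted by the unadjusted p-value of the first gene gave 26889 genes adjusted over. The last listed gene had rank 2485 by p, so that 1192 ranks above it belong to genes not analysed here. These include very small p-values: the first rank with no row was 4, and 4 of the top 20 had none. Whether the fold change threshold alone accounts for the missing rows is not known, so the largest changes and the over-representation counts given here cover the listed genes only. All tests below were therefore run on genes that the authors had selected for a difference between these groups.

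The deposited values per library are RSEM expected counts that had each been multiplied by 1 of 8 factors between 0.9784 and 1.0252, whose product is 1.0000. In each row the factors ran over the columns in 1 cyclic order whose start changed from row to row, so that a factor belonged to a cell and not to a library. The start of each row was taken as the one at which the most values, divided by their factors, were multiples of 0.01, the step at which RSEM prints expected counts. All 10152 nonzero values became such multiples, the start was unambiguous for all 1293 genes, and 56.5% of the values were whole. On simulated values the same steps returned the original counts of all 1293 genes. The recovered expected counts were rounded to whole numbers for the tests.

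The expected counts are not scaled to depth, and library totals over all genes were not used here. Over the listed genes alone the counts summed to between 354272 and 552331 per library, which is not the depth of the libraries. Size factors were set within each group by the median of ratios over genes with a mean of 50 or more and no 0 in the group. A single offset between the groups (-0.231 on the log2 scale, mutant over wild type) was then chosen so that the median difference between the fitted log2 fold changes and the authors' deposited ones was 0. With it, 96.8% of the 654 listed genes with a mean of 50 or more lay within 0.01 of the deposited log2 fold change, and the largest difference was 0.045. The between-group scale thus rests on the authors' fold changes. The design fixed in advance had named TMM; TMM over genes selected for a difference has no unchanged majority to rest on, and it was run as an alternative. The design had also foreseen no new test for a table of the authors' comparison alone; since expected counts per library were recovered, the count test was used, and the authors' own counts of genes are given beside it.

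The 2 groups were compared with edgeR 4.0.16 (R 4.3.3), with filterByExpr at its minimum count of 10 and minimum total of 15, glmQLFit and glmQLFTest. The filter left 1126 genes and removed 167. The p-values were adjusted by Benjamini and Hochberg over 26889 genes, with the 25596 genes outside the table set to a p of 1, and a gene was called at an adjusted p under 0.05. The dispersions come from the listed genes alone (common biological coefficient of variation 0.198). Standard errors were derived from the fitted coefficient and the quasi-likelihood F statistic. On data simulated from these libraries with 200 of 1293 genes changed, the comparison of mutants with wild type recovered 0% of changes of 1.5-fold, 23% of 2-fold and 78% of 4-fold, with 0 unchanged genes called and 0 called with the wrong sign. Every listed gene had been selected as changed, so the adjustment over 26889 genes was stricter in the simulation than in the data. These shares therefore do not carry over to the real comparison. It called some changes near 1.5-fold, such as oca2 (1.51-fold lower, edgeR quasi-likelihood test, adjusted p = 0.0201). Alternatives were DESeq2 1.42.0, median-of-ratios (RLE) or TMM scaling over the listed genes, no count filter, a replicate block, each library left out, a threshold of 0.01, an absolute log2 fold change of 1 or more, a mean of 50 or more, genes off the chromosome of iqgap1 and genes without clone names; a likelihood ratio test, TMM and the authors' own adjusted p were added after the data were seen. Alternatives for normalized values (pseudocount, low-value filter) did not apply to counts.

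The 42 gene lists (39 of symbols, 3 of name patterns) and the rule for naming genes were fixed before the data were examined. Symbols were matched exactly. For the 8 lists with at least 5 members in the table, the share of higher genes was compared with that of the rest of the table by Fisher's exact test (two-sided, adjusted over the 8 lists), with camera (limma 3.58.1) and a rank permutation test beside it. Over-representation of the 39 symbol lists in the table was added after the data were seen, as a one-sided Fisher's exact test against 26889 genes. Every list symbol was taken as tested, which can only understate the share of a list that was found. The test treats genes as independent, while list members can vary together (estimated correlation 0.227 for the erythrocyte list). Its p-values can therefore be too small. The 26889 genes were also not matched to the lists on expression level, so a part of level in the over-representation is not excluded. Named genes are iqgap1, iqgap2 and iqgap3; per direction the 10 called genes with the largest fold change and the 5 with the smallest adjusted p, given a mean normalized count of 50 or more and a symbol that is not a clone or placeholder name; and up to 4 members per list with the smallest adjusted p. Neither iqgap2 nor iqgap3 is among the genes analysed here, and a few genes that the rule names are not reported here. Names of sequenced clones beginning with other letter pairs than those in the rule were also treated as clone names.

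Positions were taken only as chromosome membership and gene order from the GRCz12tu assembly, which is not the authors' build, so no coordinates are given. Matching by symbol, by current symbol of the Ensembl ID and by synonym placed 882 of the 1293 genes (68.2%), under the 80% set as the minimum for such a check. The check over all genes is therefore void, and the one over genes without clone names, of which 91.8% were placed, was used. Genes of large families (protocadherins, zinc finger genes, globins, TRIM-like genes and others) can share reads with near-identical copies, so their values are uncertain; antisense and overlapping genes are uncertain too, since the strand setting is unknown. Nothing in the labels says that the pools of a group came from separate clutches, so p-values measure the spread between these pools only. All mutant pools were chosen for hemorrhage, so genotype, hemorrhage and any difference between the parents cannot be separated. Normalized counts below are recovered expected counts divided by the size factor.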

Results

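Whole-embryo RNA was measured in 8 pools of zebrafish embryos at 53 hours post fertilisation, 4 wild-type and 4 iqgap1 homozygous mutant pools selected for hemorrhage. The design text gives 20 embryos per pool. The table analysed here lists 1293 genes that the authors had selected as changed, so genes outside it, including most members of many gene lists, were not analysed here. Expected counts over the listed genes summed to between 354272 and 552331 per library. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom between libraries of the same group was 3.37.

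The mutated gene was examined first in every library. The iqgap1 transcript (ENSDARG00000078888), which encodes a scaffold protein of the actin cytoskeleton and cell junctions, was lower in all 4 mutant pools than in any wild-type pool. It had 2157 ± 54.8 normalized counts in wild type and 1057 ± 148 in the mutants (SD, n = 4 each), a log2 fold change of -1.03 ± 0.12 (SE; edgeR quasi-likelihood test, adjusted p = 0.000929). The transcript was thus still present in the mutants at this level. The authors' deposited table gives a log2 fold change of -1.03 for it with an adjusted p of 1.35e-18.

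**Figure D1:**
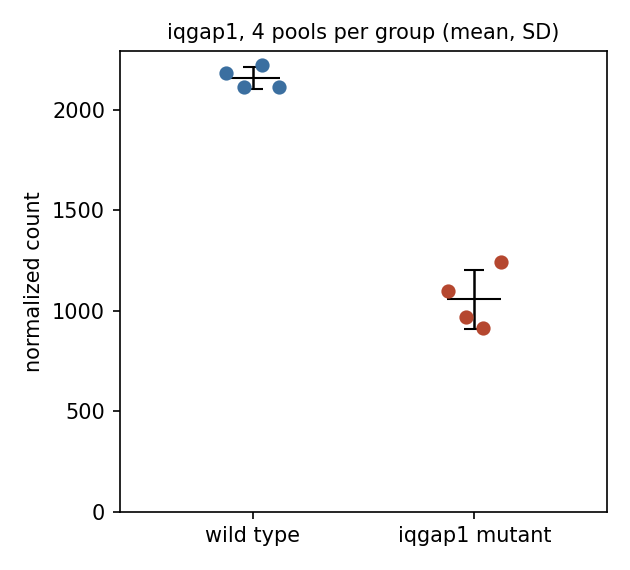
Normalized counts of iqgap1 in each pool (y axis) by genotype (x axis); points are pools, the horizontal bar is the mean and the whiskers are the SD. The 4 mutant pools averaged 1057 and the 4 wild-type pools 2157, with no overlap.

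The comparison of mutants with wild type asks which transcripts differ in hemorrhaging iqgap1 mutants. Genes with higher transcript in the mutants included embryonic globins and other erythrocyte genes, neutrophil genes and a few strongly raised single genes, while several macrophage genes were lower. Of the 1293 listed genes, 751 passed the edgeR quasi-likelihood test at an adjusted p under 0.05, 420 higher and 331 lower in the mutants. In the authors' deposited table the 1293 genes divide into 761 higher and 532 lower. The split depends on the scale between the groups: with RLE size factors over the listed genes, a log2 shift of -0.516 for every gene, 113 genes were higher and 465 lower. TMM over the listed genes, a shift of -0.385 that was tried after the data were seen, gave 162 higher and 451 lower. At an adjusted p under 0.01, 436 genes were called, and the likelihood ratio test called 1210.

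Among the called genes with a mean of 50 or more counts and a gene name, pigp, a subunit of the enzyme that starts synthesis of membrane anchors, rose most. It went from 43.9 ± 4.67 normalized counts in wild type to 415 ± 62.7 in the mutants (SD, n = 4 each), a log2 fold change of 3.24 ± 0.15 (SE; adjusted p = 3.86e-06). The transglutaminase-like gene tgm1l4 rose by a log2 fold change of 2.43, the short-chain dehydrogenase gene sdr42e2 by 2.34 and sccpdha by 2.33. The forkhead transcription factor foxq1a rose from 91.4 ± 6.24 to 422 ± 62.8 counts (log2 fold change 2.21 ± 0.14, adjusted p = 2.41e-05). The complement factor H-like gene cfhl2 rose from 180 ± 29.1 to 782 ± 37.7 counts. The protocadherin gene pcdh1g11 rose by 2.14 on the log2 scale, and adpgk2, an ADP-dependent glucokinase, by 1.57 (adjusted p = 4.31e-05). The remaining genes of the 10 with the largest rise were fosab, ptgs2b and hbbe1.1, which belong to the lists described next.

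The largest fall was that of kbtbd7, an adaptor of ubiquitin ligases, from 113 ± 22.6 normalized counts in wild type to 1.05 ± 1.21 in the mutants (SD, n = 4 each; log2 fold change -6.55 ± 0.43, adjusted p = 3.61e-05). The ecto-nucleotidase gene entpd3 had a log2 fold change of -4.79, fam198a of -4.19 and the cytochrome P450 gene cyp2x7 of -3.62. Their wild-type pools were uneven: pools 1 and 2 had 367 and 387 counts of entpd3, pools 3 and 4 had 117 and 160. Wild-type counts of fam198a (232 and 246 against 68.2 and 118) and cyp2x7 (322 and 303 against 138 and 107) divided the same way. A translation elongation factor gene, eef1a1l2, went from 1385 ± 390 to 106 ± 13.8 counts (log2 fold change -3.71 ± 0.22, adjusted p = 2.11e-05); it has near-identical copies, so its count is uncertain. The same holds for the row named RAC1, a small GTPase gene, with a log2 fold change of -3.47. RAC1 counts were lower in wild-type pools 1 and 2 (243 and 319) than in 3 and 4 (829 and 617). The gelsolin gene gsnb, which encodes an actin-severing protein, fell from 3216 ± 384 to 552 ± 170 counts (log2 fold change -2.54 ± 0.22, adjusted p = 0.000206). The glycosyltransferase gene gbgt1l3 had a log2 fold change of -2.56, the cathepsin L-like gene ctsll of -2.40 and jac1 of -2.14. Among the 5 lower genes with the smallest adjusted p were also paqr3a (-2.11), the sodium-coupled sugar transporter gene slc5a9 (-2.10) and the DNA polymerase gene polh (-1.27).

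Erythrocyte genes were higher as a group. Of 39 list symbols, 27 were in the table and all 27 were higher in the mutants, with a median log2 fold change of 1.32 (range 0.61 to 2.15). The test called 25 of them over all genes, and 27 when p-values were adjusted over the list alone. The 25 depend on the scale between the groups: with RLE size factors tfr1a went from a log2 fold change of 0.69 to 0.18 and was not called. RLE results are given here for the named genes only, so how many of the 25 kept their call is not stated. The rises of rhag (0.61) and urod (0.65) were smaller than that of tfr1a, while hbbe1.1 had the largest, 1.64 with RLE. The share of higher genes exceeded that of the rest of the table, in which 734 were higher and 532 lower (Fisher's exact test, adjusted p = 6.23e-06); the call was lost in camera with an estimated correlation (adjusted p = 0.36). The embryonic beta globin hbbe1.1 rose from 5728 ± 1391 to 25354 ± 2452 normalized counts (SD, n = 4 each; log2 fold change 2.15 ± 0.18, adjusted p = 0.000193). The red cell anion exchanger slc4a1a rose by 1.63 on the log2 scale, the heme synthesis enzyme alas2 by 1.49 and the carbonic anhydrase cahz by 1.43. The transcription factors gata1a and klf1 and the receptor gene epor were among the 27. The mean log2 level of the 27 genes was 8.91 ± 0.19 in wild type and 10.16 ± 0.04 in the mutants (SD, n = 4 each). In the list test added after the data were seen, erythrocyte symbols were over-represented in the table, with 27 found against 1.88 given by the share of all genes (one-sided Fisher's exact test, adjusted p = 1.75e-25).

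**Figure D2:**
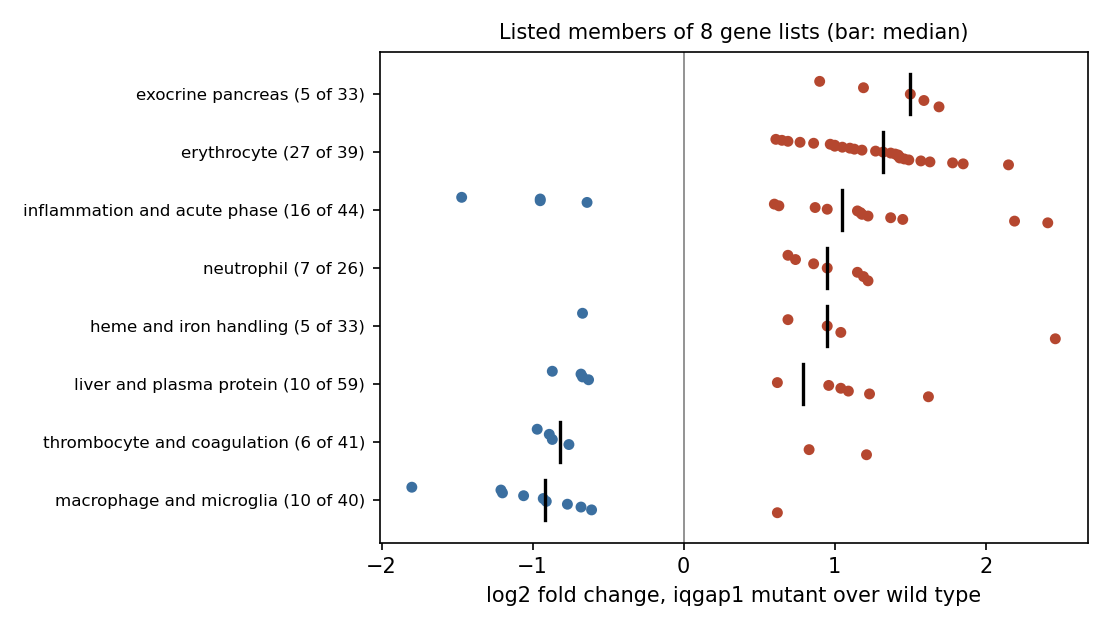
Log2 fold change (x axis, mutant over wild type) of each listed member of the 8 gene lists with at least 5 members in the table (y axis, with listed members and symbols in the list); each point is a gene and the black bar is the median. All 27 erythrocyte and all 7 neutrophil genes lie above 0, and 9 of 10 macrophage and microglia genes below.

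Macrophage and microglia genes were lower, apart from 1. Of 40 list symbols 10 were in the table, 1 higher and 9 lower, and the test called 7 of them (6 lower), or 10 adjusted over the list alone. The share of higher genes was below that of the rest of the table (Fisher's exact test, adjusted p = 0.00822). That call was lost when only called genes were counted (adjusted p = 0.0961), at a mean of 50 or more (0.0939), in the rank permutation test (0.0748) and in camera with an estimated correlation (adjusted p = 0.36). The scavenger receptor marco fell from 65.4 ± 13.2 to 18.7 ± 3.67 normalized counts (SD, n = 4 each; log2 fold change -1.80 ± 0.23, adjusted p = 0.0016). The progranulin gene grna had a log2 fold change of -1.21, the cathepsin gene ctss2.2 of -1.20 and the NADPH oxidase subunit cyba of -0.77. Of the other listed members mpeg1.1 and apoeb were lower and called, irf8, lygl1 and lgals9l1 were lower with no call, and the pan-leukocyte gene lcp1 was the higher one. The mean log2 level of the 10 genes was 7.08 ± 0.12 in wild type and 6.23 ± 0.13 in the mutants. The list was over-represented in the table (10 against 1.92, one-sided Fisher's exact test, adjusted p = 0.000188).

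Neutrophil genes were higher. Of 26 list symbols 7 were in the table, all 7 were higher and all 7 were called, over all genes and adjusted over the list alone. Their share of higher genes did not pass against the rest of the table (Fisher's exact test, adjusted p = 0.122), while the list was over-represented in it (7 against 1.25, one-sided Fisher's exact test, adjusted p = 0.00167). The matrix metalloproteinase mmp9 rose from 133 ± 9.82 to 310 ± 74.5 counts (log2 fold change 1.22 ± 0.17, adjusted p = 0.00261). The myeloperoxidase gene mpx rose by 1.15 on the log2 scale, cpa5 by 1.19 and the lysozyme gene lyz by 0.86. Of the 7, mmp9, cebpb and cpa5 are also on other lists. With RLE size factors mmp9, mpx, cpa5, lyz and cebpb were not called, so these rises depend on the scale between the groups. RLE results for npsn (0.74) and lect2l (0.69) are not given here, and their rises were smaller still. The mean log2 level was 8.26 ± 0.08 in wild type and 9.22 ± 0.15 in the mutants (SD, n = 4 each).

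**Figure D3:**
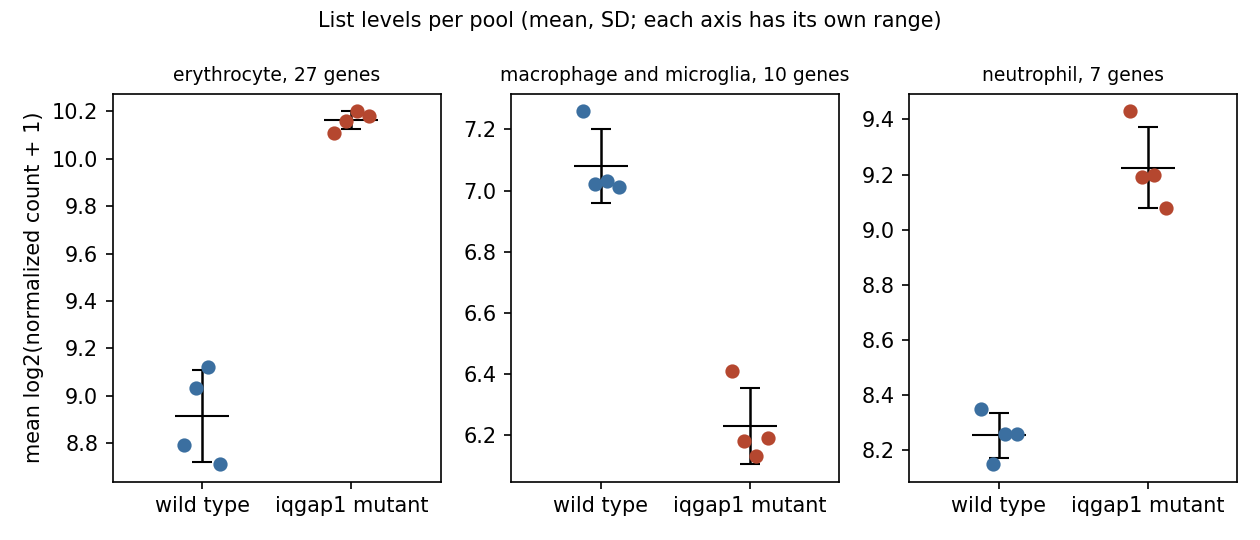
Mean log2(normalized count + 1) of the listed erythrocyte, macrophage and microglia, and neutrophil genes in each pool (y axis, its range differs by panel) by genotype (x axis); points are pools, horizontal bars means and whiskers SD. Erythrocyte levels went from 8.91 to 10.16, macrophage and microglia levels from 7.08 to 6.23 and neutrophil levels from 8.26 to 9.22.

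Inflammation and acute phase genes were over-represented in the table, with 16 of 44 symbols listed against 2.12 given by the share of all genes (one-sided Fisher's exact test, adjusted p = 1.69e-09). Of these, 12 were higher and 4 lower; the test called 10 (7 higher, 3 lower), or 15 adjusted over the list alone. The share of higher genes did not differ from the rest of the table (Fisher's exact test, adjusted p = 0.315). The Fos family transcription factor fosab rose from 61.1 ± 26.8 to 325 ± 103 normalized counts (SD, n = 4 each; log2 fold change 2.41 ± 0.31, adjusted p = 0.00174). The inducible cyclooxygenase ptgs2b rose from 42.7 ± 13.5 to 195 ± 21.5 counts (adjusted p = 0.000279). The complement genes c3a.3 and c3a.6 fell, by log2 fold changes of -1.47 and -0.95, and cfb fell by -0.64, while c3a.2 (-0.95) did not pass (adjusted p = 0.0568). The listed complement component and factor genes outside this list, looked at after the data were seen, were mostly higher: c4, c6, cfhl2, cfp and masp2 were higher and called, c3a.4 and cfbl higher with no call, and cfd and bfb lower and called. The c3a genes are near-identical copies. Of the 7 called higher genes of this list, fosab, fosb, junbb and fosl1a are immediate early genes and mmp9 and cebpb are also on the neutrophil list, which leaves ptgs2b, and nothing in the labels says whether the pools were handled alike.

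Liver and plasma protein genes moved both ways, with 6 of 10 listed members higher and 4 lower out of 59 symbols (Fisher's exact test, adjusted p = 1), and the test called 6, or 9 adjusted over the list alone. The list was over-represented in the table (10 against 2.84, one-sided Fisher's exact test, adjusted p = 0.00364). The secreted liver gene leg1.1 rose by 1.09 on the log2 scale, while the ceruloplasmin gene cp (-0.67) and the kininogen gene kng1 (-0.87) fell. Of the thrombocyte and coagulation list, 6 of 41 symbols were listed, 2 higher and 4 lower (Fisher's exact test, adjusted p = 0.315). The test called 3 of them, or 4 adjusted over the list alone. The coagulation factor gene f7 fell from 199 ± 58 to 101 ± 5.54 normalized counts and the receptor gene f2rl1.2 rose from 107 ± 15.8 to 248 ± 40.6. Of the heme and iron handling list, 5 of 33 symbols were listed and all 5 were called, 4 higher and 1 lower (Fisher's exact test, adjusted p = 0.748). The ferrireductase gene steap3 rose by 2.46 and the biliverdin reductase gene blvrb by 0.95 on the log2 scale, while cp was the lower one. Of the exocrine pancreas list, 5 of 33 symbols were listed, all higher (Fisher's exact test, adjusted p = 0.164), but only cpa5 was called; ela2l, cpa4 and erp27 were removed by the count filter and not tested. With RLE size factors leg1.1, f2rl1.2, blvrb, cpa5 and tfr1a, a further member of the heme and iron handling list, were not called.

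The position of the called genes was examined because pools can differ in the haplotype around a mutated locus. Over called genes without clone names, 19 of 402 placed protein-coding genes (4.73%) lay on the chromosome of iqgap1 in GRCz12tu, against 991 of 19562 in the annotation (5.07%; Fisher's exact test, adjusted p = 0.987). No chromosome of the 25 passed an adjusted p of 0.05 in this set. Over all listed genes without clone names 1 chromosome, not that of iqgap1, passed with fewer listed genes than its share: 12 of 624 (1.92%) against 861 of 19562 in the annotation (adjusted p = 0.0249). Over all called genes, where the check is void because too few were placed, 1 other chromosome held more, 37 of 540 (adjusted p = 0.0156). Over all listed genes, a check that is void for the same reason, 4 chromosomes passed, 2 above and 2 below their share (adjusted p = 0.0179 or lower), and that of iqgap1 did not.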

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

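Within each group of 4 pools, the highest or lowest value was set against the others by Dixon's test, for the named genes, the 8 lists and the total of expected counts over the listed genes. The tests of scaling on the erythrocyte genes, of deviations within groups and of the neutrophil genes described in this part were chosen after the results they bear on were seen; the one that leaves out mutant pools and the one without the offset between groups were chosen before. Of 188 such comparisons, 16 stood apart, where chance gives about 9.4, and genes measured in the same pools are not independent.

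Mutant pool 1 accounted for 7 of the 16. It was the highest mutant pool for pigp (509 normalized counts, others 373 to 392), slc4a1a (5656, others 4244 to 4396), alas2 (2309, others 1838 to 1882), cahz (3225, others 2454 to 2541), blvrb (1083, others 911 to 920) and kng1 (357, others 266 to 282). It was the lowest for tbx6, with 9.67 counts against 23.3 to 26. The 27 erythrocyte genes as a set were not highest in this pool. Their mean log2 level in it was 10.11, the lowest of the mutant pools, whose mean was 10.16 ± 0.04 (SD, n = 4). On the second principal component of the listed genes (7.1% of the variance) mutant pool 1 lay at 10.39, the other mutant pools between -3.67 and -2.49. Without this pool, 804 genes were called in place of 751.

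Mutant pool 2 was the highest for cnn1b (32.2 normalized counts, others 27.4 to 28) and c3a.3 (575, others 379 to 409), and mutant pool 4 for oca2 (203, others 155 to 163). Mutant pool 4 had the lowest mean log2 level of the inflammation and acute phase list, 7.65 against 7.94 to 7.95. Wild-type pool 1 had the highest mean log2 level of the macrophage and microglia list, 7.26 against 7.01 to 7.03. Wild-type pool 2 had the highest kbtbd7 (146 counts, others 97.7 to 106). Wild-type pool 4 had the lowest steap3 (2.76, others 6.51 to 6.96) and tat (33.1, others 55.7 to 59.5) and the highest cebpb (643, others 433 to 466).

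The raised erythrocyte genes were set against 2 technical explanations and 1 biological one. Scaling as the whole cause is argued against: a shift shared by all genes keeps their order, and the 27 genes ranked above the rest of the table by log2 fold change (rank permutation test, adjusted p = 0.0024). That test treats genes as independent, and the list was not called in camera with an estimated correlation (adjusted p = 0.36), which limits this argument. The size of the rise depends on the scale, since the median was 0.82 (SD over genes 0.38) with RLE size factors and 1.32 without them. A single unusual mutant pool is argued against, because the lowest median with any 1 mutant pool left out was 1.28. A larger share of erythrocyte RNA in the mutant pools remains a hypothesis: the genes varied together within groups (mean pairwise correlation 0.23), more than any of 10000 random sets matched on level (permutation p = 0.0001, the smallest these sets can give). Variation together cannot tell a larger share from a higher transcript level per cell, which was not measured. Whether a larger share would come with the genotype, with hemorrhage or with a difference in stage stays open, since the design does not separate them.

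The lower macrophage and higher neutrophil genes were weighed in the same way. The listed neutrophil genes did not fall with the macrophage genes, and their median log2 fold change was 0.95 (SD over genes 0.22). This restates the pattern for genes already selected as changed, and the size of their rise depends on the scale between the groups. A lower share of all leukocytes stays undecided, since transcript level per cell was not measured. Neutrophil genes outside the table were not analysed either. The offset between the groups lessened the macrophage fall and did not cause it, since the median of these genes was -1.15 (SD over genes 0.61) without it and -0.92 with it. These medians differ by the offset alone, so they cannot tell whether another scale would remove the fall. RLE and TMM lower every gene further, and no scale that raises the mutants more was tried. A shift of every gene leaves the distance between the macrophage and the neutrophil genes as it is. Fewer macrophages in the mutant pools may account for the fall, but the 10 genes did not vary together within groups beyond random sets (mean pairwise correlation 0.10, permutation p = 0.121), which leaves this explanation undecided with so few genes. Genes of the list outside the table were not analysed here.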

How the results depend on the processing

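The TMM scaling, the likelihood ratio test, the authors' own adjusted p and the position of all listed genes were chosen after the data were seen. So were, for the gene lists, the count of members among called genes, the preset camera fit and the RLE setting. The count of called genes (751) moved by over 1.5 times to 1210 with the likelihood ratio test, 1293 by the authors' deposited adjusted p, 436 at an adjusted p under 0.01, 487 at an absolute log2 fold change of 1 or more, 498 at a mean of 50 or more and 432 without clone or placeholder names; the last 4 count fewer genes by construction. It was 913 with DESeq2, 827 with no count filter, 578 with RLE and 613 with TMM over the listed genes, and 722 without the chromosome of iqgap1. With RLE and TMM, 19.6% and 26.4% of the calls were higher, against 55.9%; both rest here on genes selected for a difference. Without 1 library the count ranged from 535 (without mutant pool 2) to 804 (without mutant pool 1). The replicate block gave 531 genes, of which 517 were among the 751. The deviations of same-numbered pools correlated at 0.01, 0.11, -0.24 and -0.11, within the range of the other pairs between the groups (-0.37 to 0.30). They show no pairing by number, but so few pairs over selected genes cannot exclude it.

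The log2 fold change of iqgap1 was between -1.54 (RLE) and -0.97 (without mutant pool 3), called throughout. The list counts with RLE or a library left out keep the same listed genes, so their unchanged values say little. The erythrocyte list lost its call in camera with an estimated correlation (adjusted p = 0.36; 9.1e-05 with the preset one, 0.000163 with the replicate block, 0.0024 in the rank permutation test). The macrophage and microglia list lost its call among called genes (0.0961), at a mean of 50 or more (0.0939), in the rank permutation test (0.0748) and with an estimated correlation (0.36); the cause was not tested beyond the lower number of members in the first 2 of these (7 and 6 against 10). The share of higher genes in the liver list fell from above to below that of the rest of the table among called genes (3 higher and 3 lower, adjusted p = 1) and at a mean of 50 or more (3 and 4, 0.44), with no call either way. No other list changed its side of the threshold. Iqgap1's chromosome had an odds ratio of 0.989 over all called genes, a void check since too few were placed, 0.928 over those without clone names, and between 0.818 and 0.981 in the other settings, with no call. Of 68 called named genes, 18 lost their call with RLE, 9 with the replicate block and 1 to 11 with a library left out; none changed direction with DESeq2, the block or a library left out, and RLE could not turn any listed gene. Depth limits the low genes: 167 listed genes were too low to test.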

Other observations

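The tests of this part were chosen after the data were seen, apart from the fixed gene lists, the test of large changes with listed neighbours and the one that sets gene families aside. Immediate early genes, a list written after the data were seen, were higher throughout: 13 of 36 symbols were in the table, all 13 higher and 11 called, with a median log2 fold change of 1.15. Since the list was written from genes seen in the table, no test is given. Their mean log2 level was 6.58 ± 0.14 in wild type and 7.75 ± 0.17 in the mutants (SD, n = 4 each). Besides the Fos and Jun family genes they included npas4a, egr1, nr4a1, ier2a, ier2b, csrnp1a, klf4 and cyr61. These genes respond within minutes to stimuli, and nothing in the labels says whether the pools were handled alike.

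Other fixed lists had few listed members. Raised and called were abcb5 of the blood-brain barrier list (log2 fold change 0.78), klf4 of the vascular stability list (0.96), igfbp1b of the hypoxia list (1.70), gadd45ba (1.15) and casp8 (0.73) of the p53 list, tat of the glucocorticoid list (1.12), cry5 of the circadian list (0.77), the photoreceptor genes pde6b (2.09) and sagb (1.04), the muscle myosin gene myhc4 (1.29), aox5 of the pigment list (0.94) and elovl7a of the skin list (0.61). Of these raised genes abcb5, klf4, gadd45ba, casp8, tat, cry5, sagb, aox5 and elovl7a were not called with RLE size factors. Lowered and called were gsta.1 of the NRF2 list (-1.32), isg15 of the interferon list (-1.46), th of the neuron list (-0.67), plp1b of the myelin list (-1.39), cryaa of the lens list (-0.74), pnp4b (-1.83) and oca2 (-0.59) of the pigment list, anxa1a of the skin list (-0.69), myha of the muscle list (-0.80) and the linker histone gene histh1l (-1.91). Listed with no call were cnn1b of the mural cell list (-0.81), tbx6 of the Wnt list (-1.35), her4.3 of the Notch and neural progenitor lists (-1.27), pdk2b of the hypoxia and glucocorticoid lists (1.21), crybb2 (1.02), mlpha (0.81) and hist2h3c (-1.19). Of low genes that were not tested, gstp2 had -1.99, cngb3.1 -1.87, the ionocyte gene rhcgl1 -2.60 and lim2.2 1.54. The stress list had cebpb alone (0.95), the IQGAP partner list iqgap1 alone, and the ribosomal pattern matched rps6ka2 (0.71, not called), a kinase gene and not a ribosomal protein gene. The table held 0 members of the 9 lists for endothelium, heat shock, cell cycle, actin cytoskeleton and adhesion, extracellular matrix, heart, intestine, cartilage and bone, and cholesterol synthesis, whose genes were not analysed here. The name pattern for mitochondrially encoded genes matched 0 rows, but a row named after the mitochondrial genome sequence was listed as higher and called (log2 fold change 0.81).

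Large changes were more often in genes with clone or placeholder names: 193 of 274 genes with an absolute log2 fold change of 2 or more (70.4%) had such a name, against 147 of 473 under 1 (31.1%; Fisher's exact test, p = 1.28e-25). The genes were not matched on expression level, so a part of level and of the authors' selection in this difference is not excluded. The table also held 12 protocadherin genes (8 higher), 27 zinc finger genes (16 higher) and 17 TRIM-like genes (14 higher), families whose copies can share reads. In 1155 of the 1293 listed genes the groups did not overlap, where chance gives 2.9% and the authors' selection favours such genes.

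Changed genes lay close together along the chromosomes. Of 74 placed genes with a gene name and an absolute log2 fold change of 2 or more, 48 (64.9%) had another listed gene among the 5 nearest named genes on either side in GRCz12tu, more than in any of 10000 random placements (median 28.4%; permutation p = 0.0001, the smallest they can give). Genes with a change under 1 lay near listed ones as well, 121 of 310 (39.0%, permutation p = 0.0003), so that this is not confined to large changes. Neighbours sharing the first 3 letters of the symbol do not account for all of it. With those set aside, 40 of the 74 (54.1%) kept a listed neighbour, again with a permutation p = 0.0001. Tandem copies under unlike symbols were not set aside, so tandem families as a whole are not excluded. The random placements drew on all named protein-coding genes, whether or not they are expressed in these embryos. Haplotypes that differ between the parents of the pools are a candidate explanation, and neighbours regulated together stay open. Beside iqgap1, serinc4 (-0.82), leap2 (-2.45) and cyp2x10.2 (-1.71), named after their values were seen, were the listed ones among 50 named neighbours, all lower. The clone-named si:ch211-122f10.4 (-0.80) and si:dkey-286h2.3 (-1.52), also near it and lower, were outside this test of named genes. Chance placement was not excluded, since 5.49% of windows held as many listed genes in 1 direction, and the 3 of 50 could not be told apart from the 26 of 940 on the rest of the chromosome (Fisher's exact test, p = 0.177), so a haplotype carried with the mutated allele stays undecided.

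The 35 splits of the 8 libraries into 4 and 4 decide nothing about chance. Only 1 split, the real one, reached 751 called genes, and the highest of the others called 0 (edgeR quasi-likelihood test; up to 145 genes at an unadjusted p under 0.05). The listed genes had been selected on the real split, which fixes that outcome.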
